A study of Mus musculus with 12 samples.

How the data were processed

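Gene expression was measured on 12 Affymetrix MG-U74Av2 arrays, one per pooled RNA sample from mouse hippocampus. Per the labels, total RNA was extracted with TRIzol, polyA RNA was isolated from it, and biotin-labelled target was hybridised. Of the arrays, 9 held whole hippocampus and 3 held microdissected CA1, a subfield of the hippocampus. The deposited values are in the unit intensity, on a linear scale, and the submitters' processing notes name GCOS, the Affymetrix array software. The GCOS version, the expression algorithm and the scaling are not given in the sources used here, and detection calls were not used here. A trimmed mean without the highest and lowest 2% of values was 500.3 on wild-type hippocampus array 1, 500.3 to 500.4 on the 3 CA1 arrays and 3002 on the other 8 arrays. Fits with this scale as a block were run beside the others. Wild-type array 1 is the only hippocampal array of the lower scale, so within hippocampus the block equals leaving it out. Each hippocampal sample pooled 6 to 10 mice. The p-values below therefore measure the spread between pooled samples, not between mice, and the number of arrays limits the precision.

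Each array was rescaled to a trimmed mean of 1000. Values were floored at the 20th percentile of all scaled values, which was 65.7 (6.04 on the log2 scale), and then log2 transformed. Of 12488 probe sets, 66 were Affymetrix controls and were left out of the tests. A probe set was tested when it lay above the median of its own array on at least 2 arrays, whatever their group, which kept 7069 of 12422. Gene symbols came from the annotation of the array's probe sets, which gave 10833 probe sets a single symbol, 396 several symbols and 1193 none. Among the tested probe sets 6405 had a single symbol, for 5436 distinct genes. Probe set names with _f_at or _s_at mark sequences shared by related genes, so the H2 (MHC) symbols of such probe sets do not separate closely related family members.

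Samples were grouped by their titles. The reversed sample is named a transgenic sample in its title and a wild-type one in its description, and it was kept as a group of its own. Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust settings), with Benjamini-Hochberg adjustment and a threshold of adjusted p = 0.05. A fit with 5 levels (hippocampus never induced, induced and reversed, CA1 wild type and CA1 induced) gave the comparisons of induced with never-induced hippocampus, CA1 transgenic with wild type, the difference between these effects, CA1 with hippocampus, and the reversed sample. A fit with 7 levels separated 1, 2 and 5 weeks of induction, and a fit with 8 levels separated wild type from uninduced transgenic mice. In the fit with 5 levels the induced hippocampal level holds 1, 2 and 5 weeks. Differences between these times therefore count as spread in every comparison of that fit, those of CA1 included. Where a level held 1 array, that array was assumed to vary like the replicated ones. All tests were two-sided. A fold is given as "at least" where an array of the lower group lay at the floor. Differences are given on the log2 scale with their standard error (SE) from limma unless stated otherwise, and group levels with the SD over arrays.

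The comparisons, the alternatives, the rule for naming genes and 29 gene lists were fixed before the data were examined. The lists covered immediate early genes, the CREB family and its cofactors, neuropeptides, neurotrophins and growth factors, MHC class I and antigen processing, the interferon response, glutamate receptors, GABA synthesis and receptors, potassium channels, calcium channels and buffers, synaptic vesicle genes, postsynaptic genes, clock genes, heat shock and endoplasmic reticulum stress, apoptosis and DNA damage, oxidative phosphorylation, ribosomal proteins and the proteasome. They also held markers of astrocytes, oligodendrocytes, microglia and macrophages, endothelial cells and pericytes, choroid plexus, dentate granule cells, CA1 pyramidal cells, CA3 and CA2 pyramidal cells, interneurons, other brain regions and blood. Each list was tested with camera of limma at a preset correlation of 0.01, with the brightest probe set per gene, and again with an estimated correlation. The estimate uses the residuals of the fit behind the comparison. In the fit with 5 levels these hold the differences between 1, 2 and 5 weeks, so genes that change together with time raise it. Among the tested probe sets, Creb1 and Pdyn each had a dim one and a bright one, named by their mean in never-induced hippocampus. In wild-type CA1 this order does not hold for either gene. Another Creb1 probe set lay under the filter. The list tests used the bright ones, and the values given for these genes are those of the dim ones unless stated. Lists at 1, 2 and 5 weeks, in the reversed sample and on dox were tested only after the data had been seen. The named genes were the 12 largest rises and 12 largest falls past the threshold in induced hippocampus, 8 and 8 in CA1 induced against wild type, 5 and 5 in CA1 against hippocampus and 4 and 4 elsewhere. Where under 4 probe sets passed, the 10 with the smallest p were named. List members past the threshold and 11 genes fixed beforehand (Creb1, Crem, Bdnf, Pdyn, Fos, Sst, Penk, Nr4a1, H2-D1, H2-K1 and B2m) completed the rule.

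The procedure was tested on simulated data with known changes. Among 4-fold changes, 100% were called in induced against never-induced hippocampus, 97.0% at 2 weeks, 72.7% at 5 weeks, 78.8% in the reversed sample and 87.9% in CA1. Among 2-fold changes the percentages were 80.6, 50, 28.6, 38.5 and 23.1 in the same order. The simulated data held many changes of 2-, 4- and 8-fold together and drew each gene independently, without shifts shared within an array. The percentages may therefore overstate what the tests could call in the real data. Calls in one comparison were followed in others against 10000 random lists of the same size, matched on mean level; these lists do not keep the correlation between genes. The share of a rise left after reversal was the reversed value minus the never-induced mean, divided by the rise. The rise was the induced mean minus the never-induced mean for the calls of induced hippocampus, and the 5-week value minus the never-induced mean for the 5-week calls, with the 2-week and the induced mean as alternatives chosen after seeing the data. The alternatives were quantile normalization, median centring, values as deposited, no filter or a stricter one, another floor, an offset in its place, eBayes with trend and robust settings, other sample sets and control groups, a replicate block, a fold criterion without a test, and leaving out each replicate. A block for the deposited scale, the arrays of the higher scale alone, a covariate for RNA length, a count of CA1 calls less those low on the wild-type array with VC within or below the hippocampal range, and repeats from the 5-week calls were chosen after seeing the data.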

Results

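The data describe gene expression in the hippocampus of mice that carry VP16-CREB, a constitutively active form of the transcription factor CREB, under the control of doxycycline (dox). Dox keeps the transgene silent, and its withdrawal switches the transgene on. Transgenic (VC) hippocampus was sampled at 1 week (n = 2 arrays), 2 weeks (n = 2) and 5 weeks (n = 1) after dox was withdrawn. A further VC sample expressed the transgene for 3 weeks and then had it silenced with dox for 2 weeks (n = 1, reversed). Wild-type hippocampus (n = 2) and VC hippocampus kept on dox (n = 1) formed the never-induced group of 3 arrays. Microdissected CA1 came from wild-type mice (n = 1) and from VC mice 3 weeks after dox withdrawal (n = 2). Correlations of log2 values between arrays ran from 0.93 to 0.98 within hippocampus, from 0.91 to 0.95 within CA1 and from 0.83 to 0.92 between the regions. Groups of 1 array have no replicate error of their own, and their standard errors come from the pooled fit.

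With the tested probe sets, signal for Creb1, the gene that encodes CREB, was higher in each induced sample than in its uninduced counterparts. After reversal it lay between them. Its dim probe set, the one named from here on unless stated, read 6.04 and 6.33 in the wild-type hippocampi and 6.04 in VC hippocampus on dox, at or near the floor of 6.04 on the log2 scale. It read 8.31 and 8.50 at 1 week, 9.14 and 9.63 at 2 weeks, 9.15 at 5 weeks and 7.10 after reversal. In CA1 it read 6.04 in wild type and 8.86 and 9.56 in VC. The bright Creb1 probe set separated the samples less, with 6.36 to 7.66 in never-induced hippocampus, 7.68 after reversal, 6.04 in wild-type CA1 and 7.69 and 8.80 in VC CA1. It read 2.68-fold higher in induced than in never-induced hippocampus but did not pass the test (adjusted p = 0.999, limma). Another Creb1 probe set lay under the filter and did not separate the hippocampal samples. It read 6.04 to 7.19 in never-induced and 6.08 to 7.53 in induced hippocampus, and 6.04 after reversal. In CA1 it read 6.04 in wild type and 7.18 and 7.54 in VC. Whether a probe set measures the transgene, endogenous Creb1 or both is not given in the sources used here.

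The first comparison asked which genes are higher or lower in hippocampus with the transgene on, as a search for genes whose induction accompanies a facilitated late phase of long-term potentiation. Pdyn and Creb1 rose. Pdyn, which encodes the precursor of the dynorphin opioid peptides, was at least 14.0-fold higher with its dim probe set (10.29 ± 0.94 SD, n = 5, against 6.49 ± 0.40, n = 3; log2 difference 3.80 ± 0.46 SE, adjusted p = 0.0212). Creb1 was at least 7.02-fold higher (8.94 ± 0.54 SD against 6.13 ± 0.17; 2.81 ± 0.29 SE, adjusted p = 0.0104). For both genes all 5 induced arrays lay above all 3 never-induced arrays. Bdnf, a neurotrophin, was 1.65-fold higher (12.05 ± 0.22 SD against 11.32 ± 0.07) with all 5 induced arrays above the never-induced ones, but failed the correction over all probe sets (adjusted p = 0.826). Adjusted over the list alone, 3 of the 15 measured neurotrophin and growth factor genes passed: Bdnf, Igf2 (0.51) and Igfbp2 (0.57). Igf2 and Igfbp2 are also choroid plexus markers, the 2 that passed in that list.

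No other probe set passed in this comparison, although 223 of 7069 had an unadjusted p under 0.05. The remaining probe sets among the 10 with the smallest p all had an adjusted p of 0.999 in limma. They were an unnamed probe set, with a log2 difference of 1.44, H1f2 (0.97), Lamp2 (0.67), Tpm4 (0.60), Hnrnpa1 (-0.55), Rbbp6 (-0.64) and H2-M10.1 (-1.23). Of the genes fixed beforehand, Fos (1.22), B2m (0.83), Nr4a1 (0.18), Sst (-0.03) and Penk (-0.29 and -0.41 with 2 probe sets) did not pass, nor did any H2-K1 or H2-D1 probe set. Crem lay under the filter. Without wild-type array 1 the count in limma was 0 instead of 2. The deposited scale as a block is the same check, as that array is the only hippocampal one of the lower scale. With only arrays of the higher deposited scale, which leaves out the CA1 arrays as well, the count was 0 too.

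**Figure D1:**
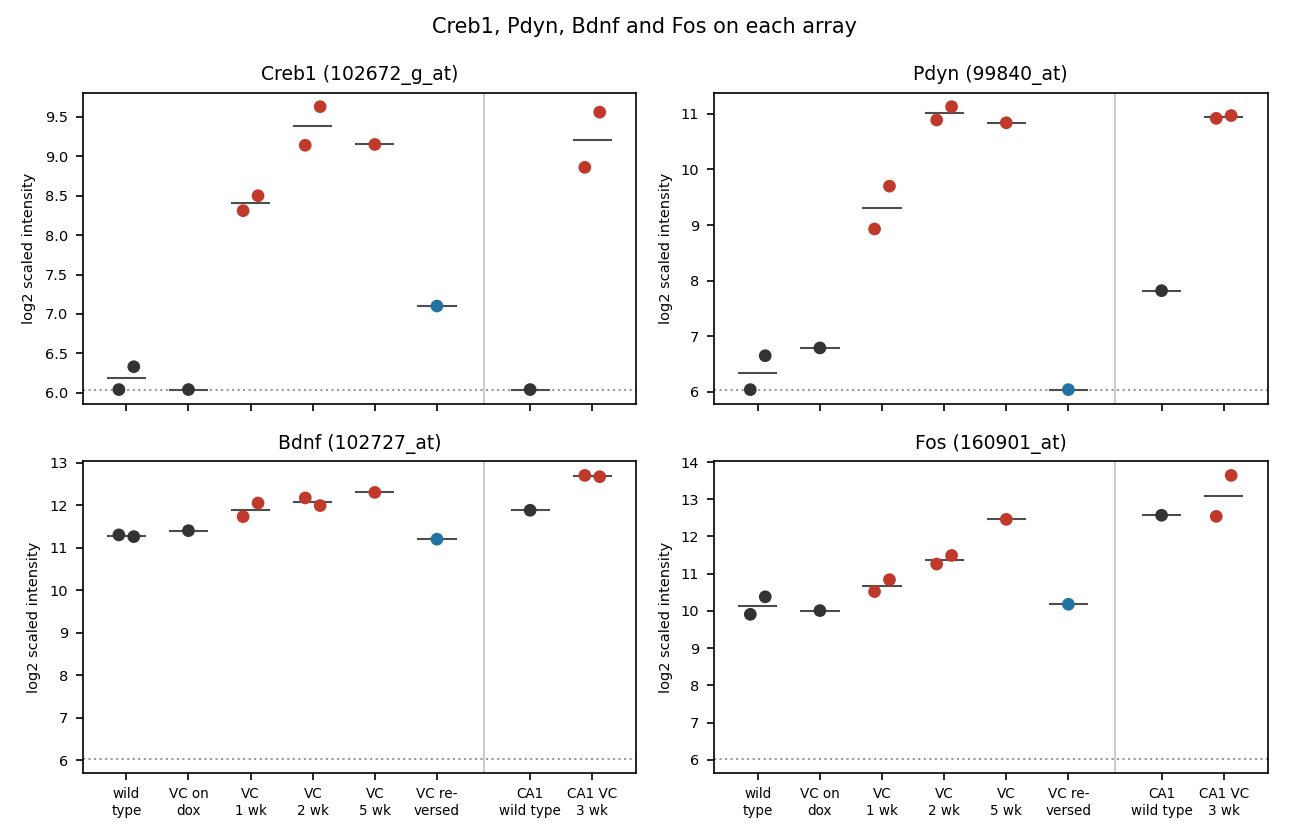
Log2 scaled intensity (vertical axis) of Creb1, Pdyn, Bdnf and Fos on each of the 12 arrays, by group (horizontal axis). Points are arrays (black: never induced or wild type; red: induced; blue: reversed), short lines group means and the dotted line the floor at 6.04; Creb1 and Pdyn lie higher on all 5 induced than on the 3 never-induced hippocampal arrays, and Fos reads 12.46 at 5 weeks.

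Several gene lists had medians above 0 in induced hippocampus, although none of their members passed the test singly. The microglia and macrophage markers had a median log2 difference of 0.71, with 20 of 22 genes positive. The MHC class I and antigen processing genes had a median of 0.64 (13 of 15 positive), and the interferon response genes 0.67 (12 of 14). The immediate early genes, which neurons transcribe within minutes of activity, had a median of 0.20 (22 of 30). With the preset correlation, 9 of 29 lists passed (8 up and 1 down). With an estimated correlation none did: the adjusted p was 0.385 for microglia, 0.385 for MHC class I, 0.484 for interferon and 0.589 for immediate early genes with an estimated correlation. Blood markers, 3 genes, had a median of 0.28 and choroid plexus markers, 8 genes, 0.32.

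Each time point was compared with never-induced hippocampus. After 1 week, Pdyn (at least 7.07-fold, 2.82 ± 0.28 SE, adjusted p = 0.0365) and Creb1 (at least 4.82-fold, 2.27 ± 0.25 SE, adjusted p = 0.0365) rose, and no other probe set passed in limma (354 had an unadjusted p under 0.05). The microglia list had a median of 0.00. Lipa, Dnajb13, Zfpm2 and Cd82 had the next smallest p, and failed (adjusted p = 0.193 for Lipa, and 0.277 for the others). All 8 choroid plexus markers were above never-induced hippocampus, with a median of 0.54 (adjusted p = 4.4e-05 at the preset correlation, adjusted p = 0.489 with an estimated correlation). The neurotrophin and growth factor list had a median of 0.10 (adjusted p = 0.0119 at the preset correlation, adjusted p = 0.736 with an estimated correlation). Ttr, a choroid plexus marker picked out after its values were seen, read 12.91 and 13.10 at 1 week against 11.35, 11.49 and 10.16 on the never-induced arrays. Neither Pdyn nor Creb1 passed without any one of the 1-week or never-induced arrays. The block for the deposited scale equals leaving out wild-type array 1.

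After 2 weeks, 11 probe sets rose and none fell (limma; 315 had an unadjusted p under 0.05). Pdyn was at least 22.9-fold (4.52 ± 0.28 SE, adjusted p = 0.000902) and Creb1 at least 9.52-fold higher. The others were a further Pdyn probe set (1.27), an unnamed one, and 7 of genes known from immune cells and glia. Cst7, which encodes cystatin F, an inhibitor of lysosomal cysteine proteases, was at least 11.9-fold higher (3.57 ± 0.36 SE, adjusted p = 0.0144). H2-Ab1, an MHC class II chain, was at least 9.79-fold higher. Irf7, a regulator of the interferon response, was 3.76-fold, Gfap, the intermediate filament of astrocytes, 3.09-fold, and Cd52, a leukocyte surface protein, 3.06-fold higher. H2-K1, an MHC class I heavy chain, rose with 2 probe sets (2.34-fold and 3.29-fold). Of the 22 microglia markers, 2 passed over all probe sets and 15 adjusted over the list alone, with a median of 0.74 (adjusted p = 0.0201 with an estimated correlation). Of the 15 MHC class I genes, 1 passed and 5 did adjusted over the list alone (median 0.54, adjusted p = 0.0416 with an estimated correlation). Of 29 lists, 9 passed at the preset correlation and these 2 also with an estimated one. With the deposited scale as a block, which equals leaving out wild-type array 1, or with only arrays of the higher scale, 3 probe sets passed instead of 11. Leaving out wild-type array 2, the array on dox or the 2-week array 1 gave 2 or 3. Without 2-week array 2, 4 were higher and 4 lower, with 3 of the 11 among them.

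After 5 weeks, 61 probe sets rose and 9 fell in the 1 pooled sample (limma; 516 had an unadjusted p under 0.05). Microglia and macrophage markers made up the largest group: of 22 measured, 13 rose, none fell and 21 were positive, with a median log2 difference of 1.84. Adjusted over the list alone, 18 passed, and the list passed with an estimated correlation (adjusted p = 0.0059). Among them were the complement genes C1qa (4.42-fold), C1qb (3.02-fold) and C1qc (3.49-fold), the signalling adaptor Tyrobp (5.65-fold), and the MHC class II genes Cd74 (7.22-fold), H2-Ab1 (at least 16.4-fold) and H2-Aa. H2-Aa lay at the floor on all 3 never-induced arrays and was at least 14.6-fold higher (adjusted p = 9.05e-05). Cst7 was at least 41.5-fold higher (5.37 ± 0.46 SE, adjusted p = 0.0022).

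Interferon response and MHC class I genes rose at 5 weeks as well. Of 14 interferon response genes 8 rose, with a median of 1.78, and 11 passed adjusted over the list alone (adjusted p = 0.0236 with an estimated correlation). Isg15, a ubiquitin-like protein induced by interferon, was 9.05-fold, Lgals3bp 5.92-fold and Ifit3 4.85-fold higher. Of 15 MHC class I and antigen processing genes 6 rose, with a median of 1.17, and 9 passed adjusted over the list alone (adjusted p = 0.0229 with an estimated correlation). They included H2-K1 (3.95-fold and 4.67-fold with 2 probe sets), H2-D1 (3.40-fold, 4.37-fold and 5.20-fold with 3), B2m, the light chain of MHC class I (4.62-fold), and the immunoproteasome gene Psmb9 (at least 6.24-fold). These lists share 3 genes. Another H2-K1 probe set did not pass (-0.07).

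Among the other lists single members rose at 5 weeks. Gfap rose 4.97-fold, the only one of 18 astrocyte markers to pass; the list had a median of 0.46 (adjusted p = 0.158 with an estimated correlation). Fos rose 5.13-fold (2.36 ± 0.39 SE, adjusted p = 0.0282), the only one of 30 immediate early genes to pass, with a list median of 0.64 (adjusted p = 0.291 with an estimated correlation); adjusted over the list alone 4 passed. Pdyn was at least 20.3-fold and Creb1 at least 8.08-fold higher. Bdnf was 1.97-fold higher and failed the correction (adjusted p = 0.0803). Among the genes that fell were Lct (-1.54) and Nr1i3 (-2.48), and Amacr, Faap20 and Adgrg3 fell to the floor, at least 6.14-fold, 6.06-fold and 5.67-fold lower. Of the 9 probe sets that fell, 8 were higher at 2 weeks than at 1 week. In VC against wild-type CA1, 5 of the 9 were lower and 4 higher.

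Of 29 lists, 10 passed at 5 weeks at the preset correlation, and only the microglia, interferon and MHC class I lists with an estimated one. Below never-induced hippocampus were the medians of the potassium channels (-0.30, with 11 of 11 genes negative), synaptic vesicle genes (-0.31), glutamate receptors (-0.23), postsynaptic genes (-0.08), calcium channels and buffers (-0.06), oxidative phosphorylation (-0.05), and the markers of dentate granule cells (-0.37), CA1 pyramidal cells (-0.22) and CA3 and CA2 pyramidal cells (-0.05). Above it were the medians of the CREB family and its cofactors (0.22), neuropeptides (0.20), neurotrophins and growth factors (0.02), GABA synthesis and receptors (0.05), clock genes (0.15), heat shock genes (0.02), apoptosis genes (0.11), ribosomal proteins (0.03) and the proteasome (0.10). The same held for the markers of oligodendrocytes (0.06), endothelial cells and pericytes (0.23), choroid plexus (0.37), interneurons (0.20), other brain regions (0.31) and blood (0.55). Potassium channels had an adjusted p of 0.181 with an estimated correlation. For the comparison as a whole, leaving out the array on dox gave 40 probe sets instead of 70, and values as deposited gave 2. With the deposited scale as a block, the same as leaving out wild-type array 1, 48 passed, and 74 with only arrays of the higher scale.

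**Figure D2:**
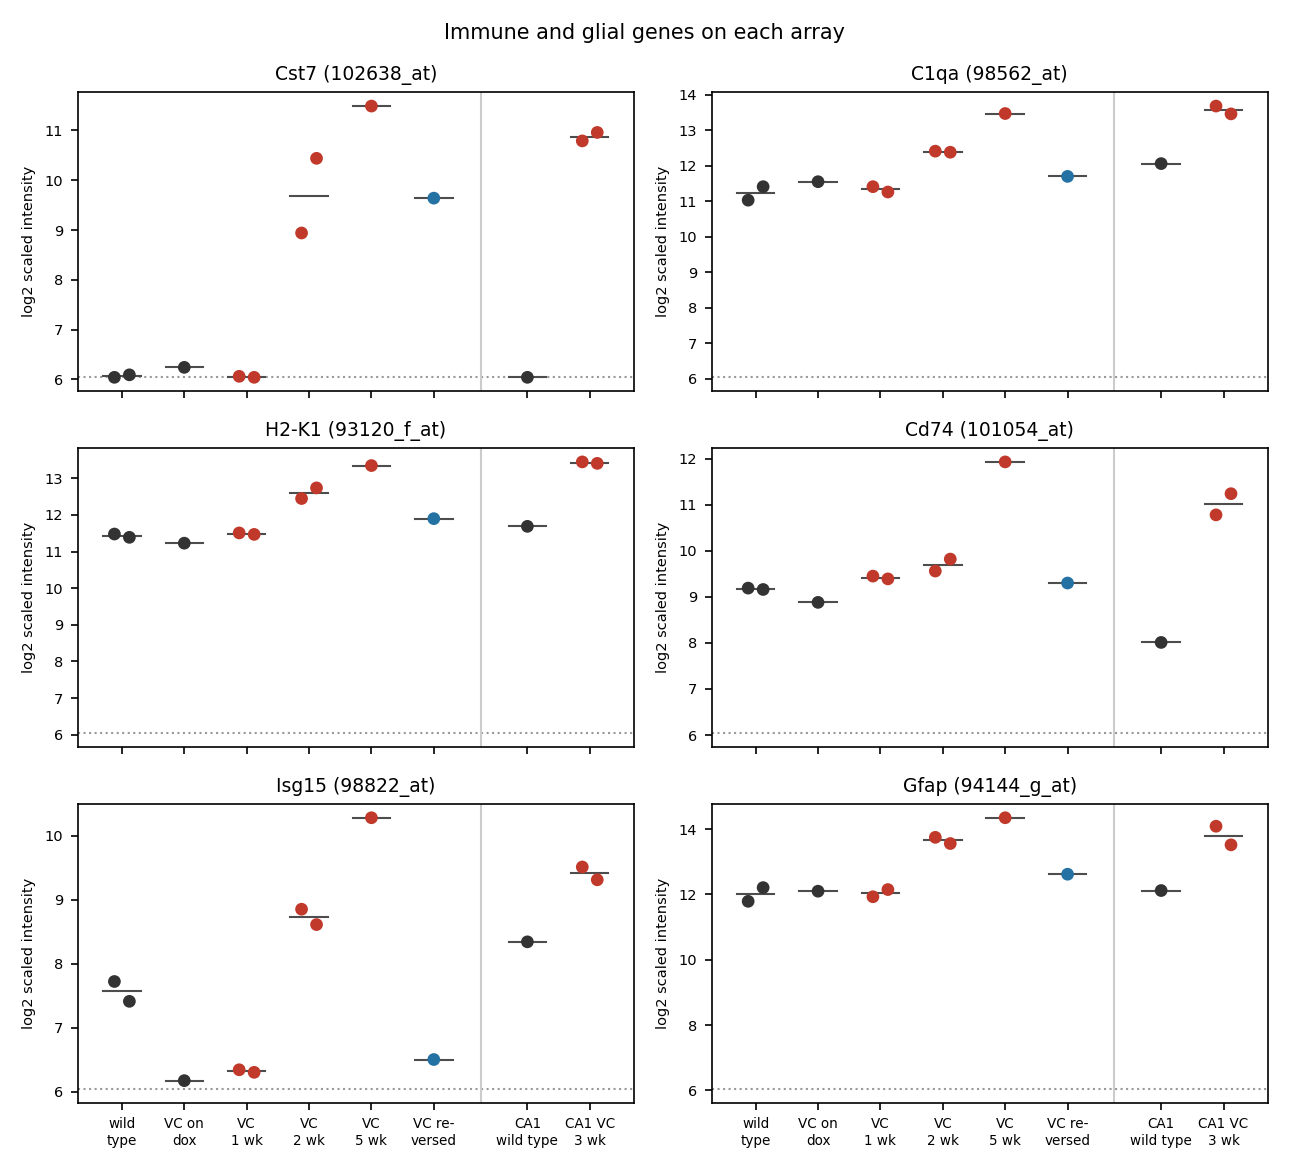
Log2 scaled intensity (vertical axis) of 6 immune and glial genes on each of the 12 arrays, by group (horizontal axis), with points, lines and colours as in the plot of Creb1 and Pdyn. Values at 5 weeks lie above those at 1 week for all 6 genes, and Cst7 reads 9.64 after reversal against 6.04 to 6.24 on the never-induced arrays.

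The direct test of time compared 5 weeks with 1 week, and 38 probe sets were higher and 7 lower at 5 weeks (limma; 484 had an unadjusted p under 0.05). Of the 38, 37 also rose against never-induced hippocampus; both comparisons use the same 5-week array. Cst7 was at least 43.5-fold, Isg15 15.5-fold, C1qc 4.02-fold and Gfap 4.94-fold higher at 5 weeks than at 1 week. H2-Aa was at least 14.6-fold and Kcne1l at least 10.7-fold higher. Of 22 microglia markers 11 were higher (median 1.91, adjusted p = 0.0066 with an estimated correlation), and 19 adjusted over the list alone. Pdyn (1.52, adjusted p = 0.229) and Creb1 (0.75, adjusted p = 0.728) did not pass. Between 2 weeks and 1 week no probe set passed in limma (672 had an unadjusted p under 0.05), with Cst7 closest (3.64, adjusted p = 0.0766). Leaving out the 1-week array 1 gave 3 probe sets in place of 45, and leaving out 1-week array 2 gave 10, while over all settings the difference ran from 1.98 to 2.04 for C1qc and from 2.18 to 2.41 for Gfap. It varied more for other genes: from 3.64 to 5.97 for Cst7, 2.05 to 4.15 for H2-Aa, 1.61 to 3.97 for Kcne1l, 0.85 to 2.95 for Psmb9 and 2.43 to 4.13 for Isg15.

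The 61 probe sets that rose at 5 weeks were followed at the earlier times. Their median log2 difference from never-induced hippocampus was 0.13 at 1 week and 0.90 at 2 weeks, and 2.10 at 5 weeks, the sample they were chosen from. At 2 weeks 58 of 61 (95.1%) were higher than at 1 week, against at most 73.8% in 10000 random lists. All 11 probe sets called at 2 weeks were among the 61, with the same never-induced arrays behind both counts.

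The reversed sample asked what remained after the transgene was silenced again. Pdyn returned to the floor, at 6.04 against 10.29 in induced hippocampus (-4.26 ± 0.68 SE, adjusted p = 0.185), which was at least 19.1-fold lower but did not pass the test with 1 reversed array. Creb1 was 7.10, with 0.345 of its rise left. Over these 2 genes the median share of the rise left was 0.113. Over the 61 probe sets of 5 weeks it was 0.166 of the rise at 5 weeks (quartiles 0.0764 and 0.322), but 0.418 of the rise at 2 weeks and 0.436 of the mean rise of the induced arrays, and 45 of 61 read above all 3 never-induced arrays. In 100 simulations of a reversed array without any change the median share of the 5-week rise left was 0.0349, and at most 0.067. These had a median of 150 calls and drew each gene independently, so they do not cover a shift shared by related genes on the 1 reversed array. More than 0.5 of the rise was left for 26 probe sets against the 2-week rise and for 5 against the 5-week rise, picked out after their values were seen: Cst7 (0.655), H2-Eb1 (0.558), an unnamed probe set (0.536), A2m (0.513) and Abca1 (0.504). The microglia list had a median of 0.37 above never-induced hippocampus (adjusted p = 0.0235 at the preset correlation, adjusted p = 0.819 with an estimated correlation).

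In limma no probe set passed for the reversed sample against never-induced hippocampus (180 had an unadjusted p under 0.05) or against induced hippocampus (181). The 10 smallest p against never-induced hippocampus belonged to Csf1r, 2.38-fold above it, and to 9 genes below it: Yif1a (-2.23), Hmces (-2.21), Psapl1 (-2.16), Lsm2 (-1.80), P3h4 (-1.62), Grb7 (-1.44), Spout1 (-1.06), Rfc1 (-0.98) and Bag2 (-0.86). The lowest adjusted p among them was 0.301. Against induced hippocampus Pdyn, Psapl1, Yif1a, P3h4 and Rnh1 had an adjusted p of 0.185.

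**Figure D3:**
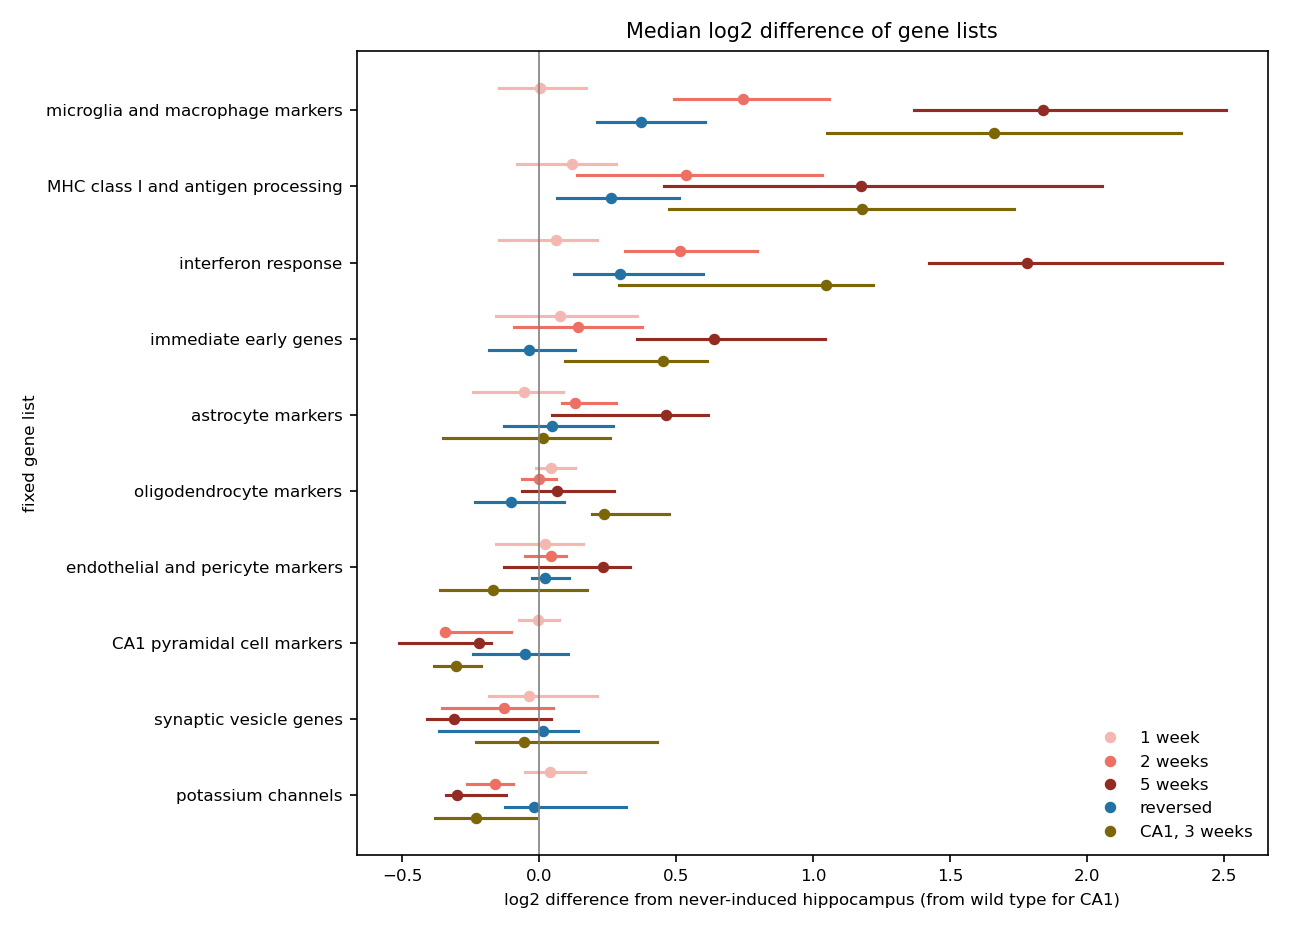
Median log2 difference of 10 gene lists (horizontal axis; points) with the quartiles over list members (lines), at 1, 2 and 5 weeks and after reversal against never-induced hippocampus, and in CA1 against wild-type CA1. The microglia markers have medians of 0.00, 0.74 and 1.84 at 1, 2 and 5 weeks, 0.37 after reversal and 1.66 in CA1.

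The CA1 arrays asked whether one subregion shows changes that whole hippocampus hides. In VC CA1 after 3 weeks 27 probe sets were higher and 6 lower than in the wild-type CA1 array (limma; 708 had an unadjusted p under 0.05). Creb1 lay at the floor in wild type and was at least 9.0-fold higher (3.17 ± 0.49 SE, adjusted p = 0.0292). Pdyn was 9.97-fold higher with its bright probe set (3.32 ± 0.44 SE, adjusted p = 0.0154) and 8.72-fold with the dim one, which did not pass (adjusted p = 0.156). With the bright probe set wild-type CA1 read 6.30, below all hippocampal arrays, and VC CA1 9.63 and 9.61, close to never-induced hippocampus (9.44 to 9.56). Immune genes rose too: Cd52 was 18.8-fold higher (11.26 against 7.02), A2m, a protease inhibitor, at least 11.8-fold and Cd14, a co-receptor for bacterial lipopolysaccharide, 5.07-fold. Ube2f (5.29-fold), Incenp (5.02-fold) and Ebi3 (5.31-fold) were the other named genes that rose. S100pbp (-1.80), Dut (-1.74), Prkd2 (-1.45) and Hrc (-1.38) fell.

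As a group, all 22 microglia markers read higher in VC CA1, with a median of 1.66; 2 passed over all probe sets (Cd52 and Cd14) and 8 adjusted over the list alone (adjusted p = 0.712 with an estimated correlation). All 15 MHC class I genes were positive as well, with a median of 1.18 and none past the test (adjusted p = 0.712 with an estimated correlation). The interferon response genes had a median of 1.05 and the immediate early genes 0.45, with an adjusted p of 0.862 for each list with an estimated correlation. This correlation came from the fit that counts differences between 1, 2 and 5 weeks in hippocampus as spread. Failing under it therefore does not show that a list did not shift. The VC CA1 arrays differed for the immediate early genes. Against never-induced hippocampus their median was 0.792 in wild-type CA1, 0.449 on VC array 1 and 1.53 on VC array 2. The B1 repeat signal was 22340, 7896 and 536 in the same order. Bdnf was 1.75-fold higher (0.81 ± 0.23 SE, adjusted p = 0.233). All 61 probe sets that rose at 5 weeks in hippocampus were higher in VC than in wild-type CA1, with a median of 1.61, against 47.9% of all tested probe sets and at most 72.1% in random lists. Of the 27 probe sets, 21 (77.8%) lay lower on the wild-type CA1 array than on all 9 hippocampal arrays while VC CA1 lay within or below the hippocampal range, as did 33.7% of all tested probe sets; Pdyn was one of them, and the choice of the 27 against this 1 array favours low values on it. The 18S ribosomal RNA signal was 14776 on that array and 3941 and 6192 on the VC CA1 arrays. Leaving out VC CA1 array 1 gave 143 probe sets instead of 33, and without the filter the balance turned to 107 higher and 185 lower. An offset in place of the floor, a floor at the 40th percentile and values as deposited each left 0 of the 33, and 0 of the 4 for the difference of effects. Taking these 21 away leaves 12 of the 33, and 26 of the 27 higher ones lay lower on the wild-type CA1 array than on all hippocampal arrays.

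The difference between the CA1 effect and the hippocampal effect was tested directly. It was larger in CA1 for 4 probe sets: Ube2f (2.62 ± 0.36 SE), Plod3 (2.49 ± 0.35 SE), Rapsn (2.23 ± 0.27 SE) and Cyb561 (2.13 ± 0.30 SE), each with an adjusted p of 0.0497 in limma, and 411 had an unadjusted p under 0.05. For these genes the wild-type CA1 array read between 6.04 and 7.16, below all 9 hippocampal arrays. Creb1 (0.36 ± 0.57 SE), Bdnf (0.08 ± 0.27 SE) and Pdyn (-0.68 ± 0.89 SE) did not pass. With the deposited scale as a block the count was 0, and leaving out VC CA1 array 1 or 2 gave 34 or 13. Without the filter 61 were higher and 167 lower.

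CA1 and whole hippocampus differed in 2539 of 7069 probe sets, with 807 higher and 1732 lower in CA1 (limma; 3331 had an unadjusted p under 0.05). Choroid plexus markers were lower: Ttr, the transthyretin carrier, was 19.3-fold lower (-4.27 ± 0.89 SE, adjusted p = 0.0051), and 6 of 8 markers fell (list median -1.15, adjusted p = 0.851 with an estimated correlation). Dentate granule cell markers fell in 5 of 11 cases, among them Dsp (-1.23) and Neurod1 (-0.94). The bright probe set of Pdyn was another (-1.95), with 6.30 in wild-type and 9.63 and 9.61 in VC CA1, while the dim one was 0.99 and did not pass (adjusted p = 0.105). Of 20 endothelial and pericyte markers 9 rose and none fell, such as Cldn5 (1.40) and Cdh5 (1.31; list adjusted p = 0.365 with an estimated correlation). Among 30 immediate early genes 14 were higher, including Fosb (2.54), Fos (2.13) and Atf3 (2.03), and 2 lower (list median 0.80, adjusted p = 0.851 with an estimated correlation). Of 19 synaptic vesicle genes 9 fell, including Vamp1 (-2.25) and Syp (-0.76). Microglia markers (median 0.83, 6 higher and 1 lower of 22) and interferon response genes (median 0.57) had an adjusted p of 0.851 with an estimated correlation. Induced CA1 was at 3 weeks and induced hippocampus at 1, 2 and 5 weeks, so region and time of induction are mixed here. Against never-induced hippocampus the microglia median was 0.32 in wild-type CA1 and 1.76 and 2.07 in VC CA1. The interferon median was 0.34 in wild-type CA1 and 1.32 and 1.38 in VC CA1. CA1 pyramidal cell markers went both ways, with Pou3f1 (0.68) higher and Hpca (-0.76), Lmo4 (-0.74) and Dcn (-0.75) lower.

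Bdnf was 1.51-fold higher in CA1 (adjusted p = 0.00814), and Penk rose with 1 of 2 probe sets (2.19). Beyond the lists, Socs3, a feedback inhibitor of cytokine signalling, lay at the floor on the hippocampal arrays of these groups and was at least 23.1-fold higher in CA1. Mep1b (8.21-fold), Zfp36 (7.81-fold), Il1a (at least 7.84-fold) and Hipk2 (6.01-fold) were also higher, and Rpl41 (9.31-fold), Tmbim1 (6.99-fold), Dmtf1 (6.35-fold) and Prss30 (6.15-fold) lower. The pyruvate carboxylase 3' to 5' ratio was 4.91 to 6.73 on the CA1 arrays and 2.07 to 3.79 on the hippocampal arrays. All 3 CA1 arrays but only 1 hippocampal array had the lower deposited scale. With that scale as a block, 288 probe sets passed (63 higher and 225 lower). The block then rests on the difference of this 1 hippocampal array from the other never-induced arrays. The median of all probe sets was -0.13, so directions are relative to it; it was -0.03 with quantile normalization, 0.16 with median centring and -2.28 as deposited. Median centring turned the balance to 1834 higher and 884 lower, and values as deposited gave 1 higher and 6801 lower.

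VC hippocampus on dox was compared with wild type to see the effect of the transgene while dox held it silent. No probe set passed in limma (100 had an unadjusted p under 0.05). Creb1 read 6.04 against a wild-type mean of 6.18, Pdyn 6.79 against 6.34 and Bdnf 11.40 against 11.28. The 10 smallest p belonged to Cideb (-1.91), Lgi4 (-2.02), Irf9 (-2.08), Isg15 (-1.40), Notch1 (-2.43), Bag3 (-1.36), Nup107 (-1.51), Clcn1 (1.16), Tcf7l1 (1.10) and Xrcc1 (1.16), with a lowest adjusted p of 0.896. The interferon response genes had a median of -0.23, with 13 of 14 negative (adjusted p = 8.87e-06 at the preset correlation, adjusted p = 0.224 with an estimated correlation). Heat shock genes (median 0.22, adjusted p = 4.36e-05) and choroid plexus markers (-0.33, adjusted p = 0.0228) passed at the preset correlation as well, with an adjusted p of 0.607 and 0.502 with an estimated correlation.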

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

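The tests in this part were chosen after the results had been seen, except the counts over splits of the arrays. The rise of immune and glial genes at 5 weeks rests on 1 pooled sample, and 45 probe sets differed between 5 weeks and 1 week. Several checks below use all 61 probe sets higher at 5 weeks. Of these, 53 had a single gene symbol and 31 belonged to the microglia, astrocyte, MHC class I or interferon lists. The 61 also include Creb1, Pdyn and Fos. For the 61 probe sets higher at 5 weeks, a single deviating array is not what the CA1 arrays show. Of them 100% were also higher in VC than in wild-type CA1, against at most 72.1% in random lists. These lists ignore the correlation between genes, and CA1 has 1 wild-type array. For the 9 probe sets that fell at 5 weeks a single deviating array stays open. In VC CA1 5 of them were lower and 4 higher, and 8 of the 9 were higher at 2 weeks than at 1 week. Haemoglobin was higher at 5 weeks by 0.725 ± 0.275 SE, below the median of 2.10 for the 61. As the 61 were chosen for a large difference on that array, this cannot decide on blood at 5 weeks. In VC CA1, where the 61 were not chosen, blood does not account for the size of their rise. Haemoglobin was higher there by 0.0466 ± 0.309 SE, against a median of 1.61 for the 61. Both SEs treat the haemoglobin probe sets as independent. A lower share of neurons that raises all glia alike does not account for the rise at 5 weeks. The microglia median exceeded the oligodendrocyte median by 1.77 at 5 weeks, with an SE of 0.302 over list members, not over samples. This comparison cannot exclude a loss of neurons with a response of microglia alone, which would leave oligodendrocyte markers unchanged. A longer time of transgene expression may explain the rise, since 95.1% of the probe sets were already higher at 2 weeks than at 1 week (at most 73.8% in random lists), but age and time off dox run with it. A difference between arrays unrelated to the transgene cannot be told apart from it: the same probe sets differed by a median of 0.0298 between never-induced arrays and 0.821 between 2 weeks and 1 week, but these never-induced arrays lie 11.3 apart on the leading axis of difference and the later weeks 28 from 1 week.

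For the probe sets called higher in VC CA1 as a set, low values on the only wild-type CA1 array and the transgene cannot be told apart. At 5 weeks in hippocampus 12 of the 27 were higher and 15 lower. Yet 4 of them were among the 61 that rose there, against 0.23 if independent: Creb1 (3.01), Cd52 (2.48), A2m (1.73) and the bright Pdyn probe set (1.01). That comparison uses no CA1 value. Cd52, A2m and Pdyn also lay lower on the wild-type CA1 array than on all 9 hippocampal arrays. Of the 27, 77.8% were low on that array with VC within or below the hippocampal range, against 33.7% of all tested, but the 27 were chosen by their difference from this array, which favours such values. Of the 27, 55.6% were higher in induced hippocampus, within the 85.2% reached by random lists. The 4 probe sets with a larger effect in CA1 than in hippocampus, Rapsn (2.23), Ube2f (2.62), Cyb561 (2.13) and Plod3 (2.49), were all low on that array. A second wild-type CA1 sample would separate these readings.

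Whether the number of calls in induced hippocampus could arise by chance is not settled by splits of the arrays. Of 56 ways to split the 8 arrays, 3 gave at least the 2 calls of the real split. Of these 1 gave 32, with the never-induced and 1-week arrays against the 2-week and 5-week arrays, and another gave 4. The split with 32 follows the time of induction, so the splits are not free of differences between the groups. Between CA1 and hippocampus only 1 of 100 splits drawn, the real one with 2663 calls in a fit of 2 groups, reached that number, and the next gave 661. The 18S ribosomal RNA signal was 7724 on the 1-week array 2, with the nearest induced array at 2629. On the same 5 induced hippocampal arrays, which span 1, 2 and 5 weeks, 30 measures were examined. They were named probe sets and array quality measures, and 1 was past the limit, for which chance gives 1 in 20 per measure.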

How the results depend on the processing

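The blocks for the deposited scale, the arrays of the higher scale alone, the covariate for RNA length, the count of CA1 calls less those low in wild-type CA1 with VC in or below the hippocampal range, and the shares of other rises left after reversal were chosen after the results had been seen. Of 146 alternative values, 74 stayed close and 72 moved; within hippocampus and within CA1 none turned a direction of a gene named past the threshold. For CA1 against hippocampus, counted after the results had been seen, quantile normalization and median centring turned 0 of the 72 higher and 89 lower named probe sets, and values as deposited turned 65 of the 72. The counts at 5 weeks (70), at 5 weeks against 1 week (45) and for CA1 against hippocampus (2539) stayed within 1.5 times under most settings, though not always with the same probe sets: without the filter 38 of the 70 and 15 of the 45 were shared, and with median centring 1691 of the 2539. Where a count moved, the cause was not tested; values as deposited mix 2 scales, and settings that leave out arrays or probe sets have fewer of them. Only 0.127% to 0.82% of tested values per array lay at the floor, but Creb1, Pdyn, Cst7 and H2-Aa lie at or near it without the transgene, so their folds and calls depend on it. Counts of calls follow, in place of 2 for induced hippocampus, 33 for VC CA1, 4 for the difference of effects, 2 at 1 week and 11 at 2 weeks.

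Quantile normalization gave 9 for the difference of effects and 0 at 1 week. Values as deposited gave 5 for induced hippocampus, 0 for VC CA1, 0 for the difference of effects, 6802 for CA1 against hippocampus, 0 at 1 week, 2 at 2 weeks, 2 at 5 weeks and 1 at 5 weeks against 1 week, with a median share of the rise left after reversal of 0.445 in place of 0.113. With them the median of all probe sets was 0.85 in induced hippocampus, against -0.02 with the trimmed mean. Without a filter the counts were 0 for induced hippocampus, 292 for VC CA1 (107 higher and 185 lower), 228 for the difference of effects (61 higher and 167 lower), 5 at 1 week, without Pdyn and Creb1, 6 at 2 weeks and 27 on dox in place of 0. With the stricter filter they were 1 for induced hippocampus, 9 for VC CA1 and 1 at 1 week, with a share left of -0.119. A floor at the 40th percentile gave 0 for induced hippocampus, VC CA1, the difference of effects and 1 week. With that floor and without the filter no share left was computed, as no probe set was called in induced hippocampus. An offset in place of the floor gave 0 for VC CA1 and the difference of effects and 1 at 1 week. Trend and robust settings gave 14 for VC CA1, 2 for the difference of effects and 1 at 1 week.

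For induced hippocampus the 9 hippocampal arrays alone gave 1, wild type alone as control 0, the 6 numbered arrays 0 with and 0 without the replicate block, and 1.5-fold without overlap 55. The replicate numbers did not pair samples (correlations 0.0422, 0.0234 and -0.0968). The fit with 8 levels gave 64 for VC CA1. Leaving out wild-type array 1, wild-type array 2, the array on dox or 2-week array 1 gave 0 for induced hippocampus, and 2-week array 2 or the 5-week array gave 1. At 1 week leaving out single arrays gave 0, or 1, another probe set, without wild-type array 1. At 2 weeks it gave 3, 2 and 2 without wild-type array 1, wild-type array 2 and the array on dox, 3 without 2-week array 1 and 8 without 2-week array 2 (4 higher and 4 lower). It gave 40 at 5 weeks without the array on dox, and 3 and 10 at 5 weeks against 1 week without 1-week arrays 1 and 2. Without VC CA1 array 1 or 2 the counts were 143 and 43 for VC CA1 and 34 and 13 for the difference of effects.

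With the deposited scale as a block, counts were 0 for induced hippocampus, 0 for the difference of effects, 288 for CA1 against hippocampus, 1 at 1 week, 3 at 2 weeks and 48 at 5 weeks. Except for CA1 against hippocampus, this block equals leaving out wild-type array 1. The 1 at 1 week, here and with only the higher scale, was neither Pdyn nor Creb1. With only arrays of the higher scale they were 0 for induced hippocampus, 1 at 1 week, 3 at 2 weeks and 74 at 5 weeks. The covariate for RNA length gave 1 at 1 week and 7 at 2 weeks, 62 at 5 weeks and 33 at 5 weeks against 1 week. Taking away the 21 of these calls low in wild-type CA1 left 12 for VC CA1, by subtraction and with no new fit. For the 61 probe sets of 5 weeks the share left was 0.166 of the 5-week rise, 0.418 of the 2-week rise and 0.436 of the mean induced rise. With an estimated correlation 0 gene lists passed for induced hippocampus, VC CA1 and CA1 against hippocampus, in place of 9, 4 and 5. These comparisons use the fit with 5 levels, whose residuals include the differences between 1, 2 and 5 weeks. In CA1 against hippocampus, median centring turned the median of the CA1 pyramidal cell markers from -0.26 to 0.03, of the potassium channels from -0.25 to 0.03 and of the calcium channels and buffers from -0.18 to 0.11. It also turned the medians of circadian clock, heat shock, apoptosis, oxidative phosphorylation, astrocyte and oligodendrocyte genes from lower to higher, and quantile normalization turned that of the GABA genes from 0.01 to -0.02.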

Other observations

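The tests in this part were all chosen after the results had been seen. Some values of genes chosen after their values were seen are given without an explanation. Ttr read 12.91 and 13.10 at 1 week but 8.64 and 12.15 at 2 weeks and 9.21 after reversal. Npy read 12.56, 12.82 and 12.89 at 2 and 5 weeks and 11.61 to 11.93 on the never-induced arrays. With 1 of 2 probe sets each, Atf3 read 10.22 and 10.35 at 2 weeks, 10.43 at 5 weeks and 8.77 to 9.11 on the never-induced arrays, and Gadd45b 10.59 and 10.35, 10.68 and 9.24 to 9.64.

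The leading axis of difference among the 9 hippocampal arrays, with 26.5% of the variance, did not follow the transgene. Induced and never-induced arrays differed by 4.88 in its score, with an exact permutation p of 0.661 over 56 splits. The axis may follow RNA length, since its correlation with the pyruvate carboxylase 3' to 5' ratio was 0.776 (exact p = 0.0129, or 0.0645 after adjustment over 5 measures). Without the 2 arrays with the most extreme ratios it was 0.586 (exact p = 0.168), so this cannot be settled here. A difference with time among the induced arrays, with scores of -20.6 and -5.42 at 1 week, 20 and 11.5 at 2 weeks and 13.4 at 5 weeks, stays open.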
